A study of Mesocricetus auratus with 36 samples.

How the data were processed

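Raw gene counts were used as deposited by the authors, 1 table per library. Per the file headers, fragments were assigned with featureCounts 2.0.1 to exons of the RefSeq annotation of golden hamster assembly BCM_Maur_2.0, summed by gene, paired-end and unstranded, from alignments whose file names carry the name STAR. The aligner's version and settings are not given in the sources used here. Per the labels, the tissue was the hypothalamic ependymal region cut out by laser capture, RNA integrity numbers lay between 7 and 9, libraries were made by BGI and sequenced on an Illumina HiSeq instrument. Because counting was unstranded, reads from antisense or overlapping genes cannot be told apart. The tables held 32340 genes, of which 31426 had a count in any library and 31895 matched the RefSeq gene table by name; 16016 carry no informative name. No table column was left unused and no pair of libraries was identical.

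Genes were filtered with filterByExpr (17926 tested), scaled with TMM and fitted in 1 robust quasi-likelihood model of all 36 libraries with edgeR 4.0.16 in R 4.3.3. Adjusted p values are Benjamini-Hochberg over the genes tested, and a gene passed below 0.05. Gene p values are from that fit unless another tool is named. Normalised CPM use the TMM factors, and log2 CPM a prior count of 2. Means ± SD are over 6 animals. The comparisons of neighbouring stages, of refractory with interbout euthermia and with long photoperiod, the 35 gene lists and the naming rule were set before the data were examined.

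The genes named are the 8 largest rises and the 8 largest falls by log2 fold change among genes that passed, with a mean log2 CPM of at least 1 and an informative name. Added to these were the members with the smallest p of each list that was called or had at least 3 changed members, and fixed genes, among them Dio2, Dio3, Tshr, Gpr50, Rax, Vim, Nes, Rbm3, Cpt1a, Pdk4, Slc2a1 and Slc16a1. Of the 35 lists, 33 had at least 5 members tested; erythrocyte markers (3 tested) and cold-inducible RNA-binding genes (1 tested, Rbm3) are given as values. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation, and p values were adjusted over the 33 lists. Counts adjusted over the list alone use the p values of its members only.

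Alternatives planned before the data were examined were RLE factors, DESeq2 1.42.0, limma voom with quality weights, a filter of 1 CPM in 6 libraries, no filter beyond 1 count, the replicate number as a block, the mean log2 CPM of neuron and oligodendrocyte markers as covariates, 2 surrogate variables (sva 3.50.0), a fit of the 2 groups compared alone, long photoperiod 1 to 3 or 4 to 6 alone, and leaving out each library in turn. The fits without the 3 libraries above 5% ribosomal RNA, and with ribosomal RNA and mitochondrial genes removed, were chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

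The workflow was tested on simulated data for each of the 6 main comparisons, with 200 genes changed. Of genes changed 2-fold it recovered 71.7% (pre-hibernation against long photoperiod), 66% (late pre-hibernation against pre-hibernation), 67% (interbout euthermia against late pre-hibernation), 58% (torpor against interbout euthermia), 63% (refractory against interbout euthermia) and 64% (refractory against long photoperiod). At 4-fold it recovered 89%, 91%, 83.8%, 92%, 87% and 84.7%, with 0 in the wrong direction. False calls made up 3.5%, 5.2%, 7.7%, 1.9%, 3.8% and 6.2% of the calls. A list shifted by 0.5 was found in all 6 simulations and 0 other lists were called. The simulated genes varied independently of each other and no library was made aberrant. False list calls at the preset correlation were therefore unlikely there, and these rates need not hold for the real libraries.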

Results

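RNA was sequenced from the ependymal strip of the mediobasal hypothalamus, cut out by laser capture from 36 male golden hamsters (Mesocricetus auratus), 6 animals in each of 6 groups. The strip is enriched for tanycytes, the glial cells that line the floor and lower walls of the third ventricle and contact the cerebrospinal fluid. To follow this tissue through the hibernation season, hamsters on a long photoperiod (14 h of light, 22 °C, 8 months old per the labels) were compared with hamsters moved to 10 h of light and 8 °C. The moved animals were taken at 4 weeks (pre-hibernation, 4 months old) and at 8 to 12 weeks before any torpor (late pre-hibernation, 6 months old). After 3 cycles of torpor and arousal they were taken 23 h into interbout euthermia, the warm interval between torpor bouts, or 13 h into torpor (both 6 months old). The refractory animals (8 months old) had stopped hibernating on their own at about 20 weeks and were taken at least 2 weeks after their last bout. The protocol has long photoperiod animals taken both before the change of day length and at the end, so the age of some of them is uncertain. Day length, ambient temperature and age differ together between several groups and cannot be told apart in this design.

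The 36 libraries held 5.16 to 28.54 M counts (M, 1e6), with a median of 22.44 M. In 33 libraries genes of ribosomal RNA took under 1% of the counts. The other 3 libraries were refractory 4 (41.8% on ribosomal RNA genes and 18.3% on mitochondrial genes, 5.16 M counts), pre-hibernation 5 (9.28% and 11.8%, 12.74 M counts) and interbout 6 (7.21% and 14.3%, 14.11 M counts). These 3 are called the rRNA-rich libraries, and each count of changed genes is also given without them, a choice made after seeing the data. Values are mean normalised counts per 1e6 counts (CPM) ± SD with n = 6, or log2 fold changes ± SE between groups of n = 6.

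**Figure D1:**
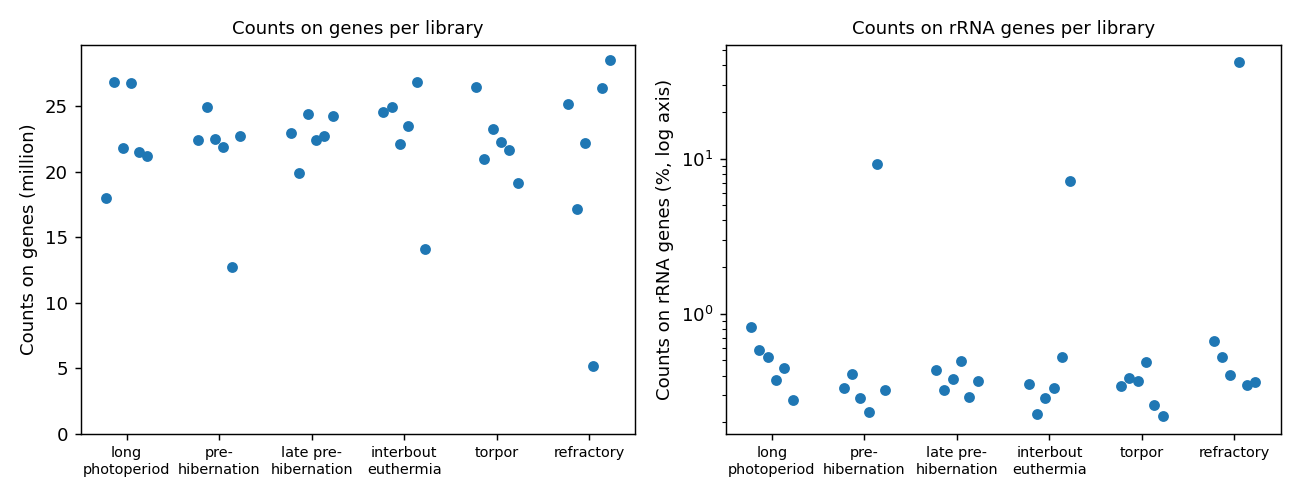
Total counts in M (left) and the share of counts on ribosomal RNA genes in percent, on a log axis (right), for each of the 36 libraries, by group. Refractory 4 holds 5.16 M counts with 41.8% on ribosomal RNA genes, and pre-hibernation 5 and interbout 6 are the other libraries above 5%.

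Over the season, Dio2, which makes the active thyroid hormone, and Dio3, which breaks it down, were each highest in a different group. Dio2 stood at 44.7 ± 20.1 CPM on long photoperiod, 5.30 ± 1.68 in pre-hibernation, 5.07 ± 1.502 in late pre-hibernation, 17.4 ± 11.2 in interbout euthermia, 7.24 ± 3.54 in torpor and 5.06 ± 1.92 in the refractory group. Dio3 stood at 5.70 ± 2.61, 46.1 ± 26.1, 20.4 ± 8.88, 7.49 ± 6.00, 37.4 ± 47.9 and 6.21 ± 2.65 CPM in the same order. Of the 17926 genes tested, 2625 differed among the 6 groups, and 4952 without the 3 rRNA-rich libraries. Among the 2625 genes, the mean was lowest in torpor for 833.

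On assembly BCM_Maur_2.0 the annotated genes span 27438872 to 27452933 (Dio2), 9080896 to 9083086 (Dio3) and 31690898 to 31694299 (Fos) of 1 contig. Lrat spans 72351916 to 72363408, Cryab 29418088 to 29421372 and Nr1d1 76508439 to 76515642 on 3 other contigs. All 6 are annotated as protein-coding, and counts were taken over their exons.

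**Figure D2:**
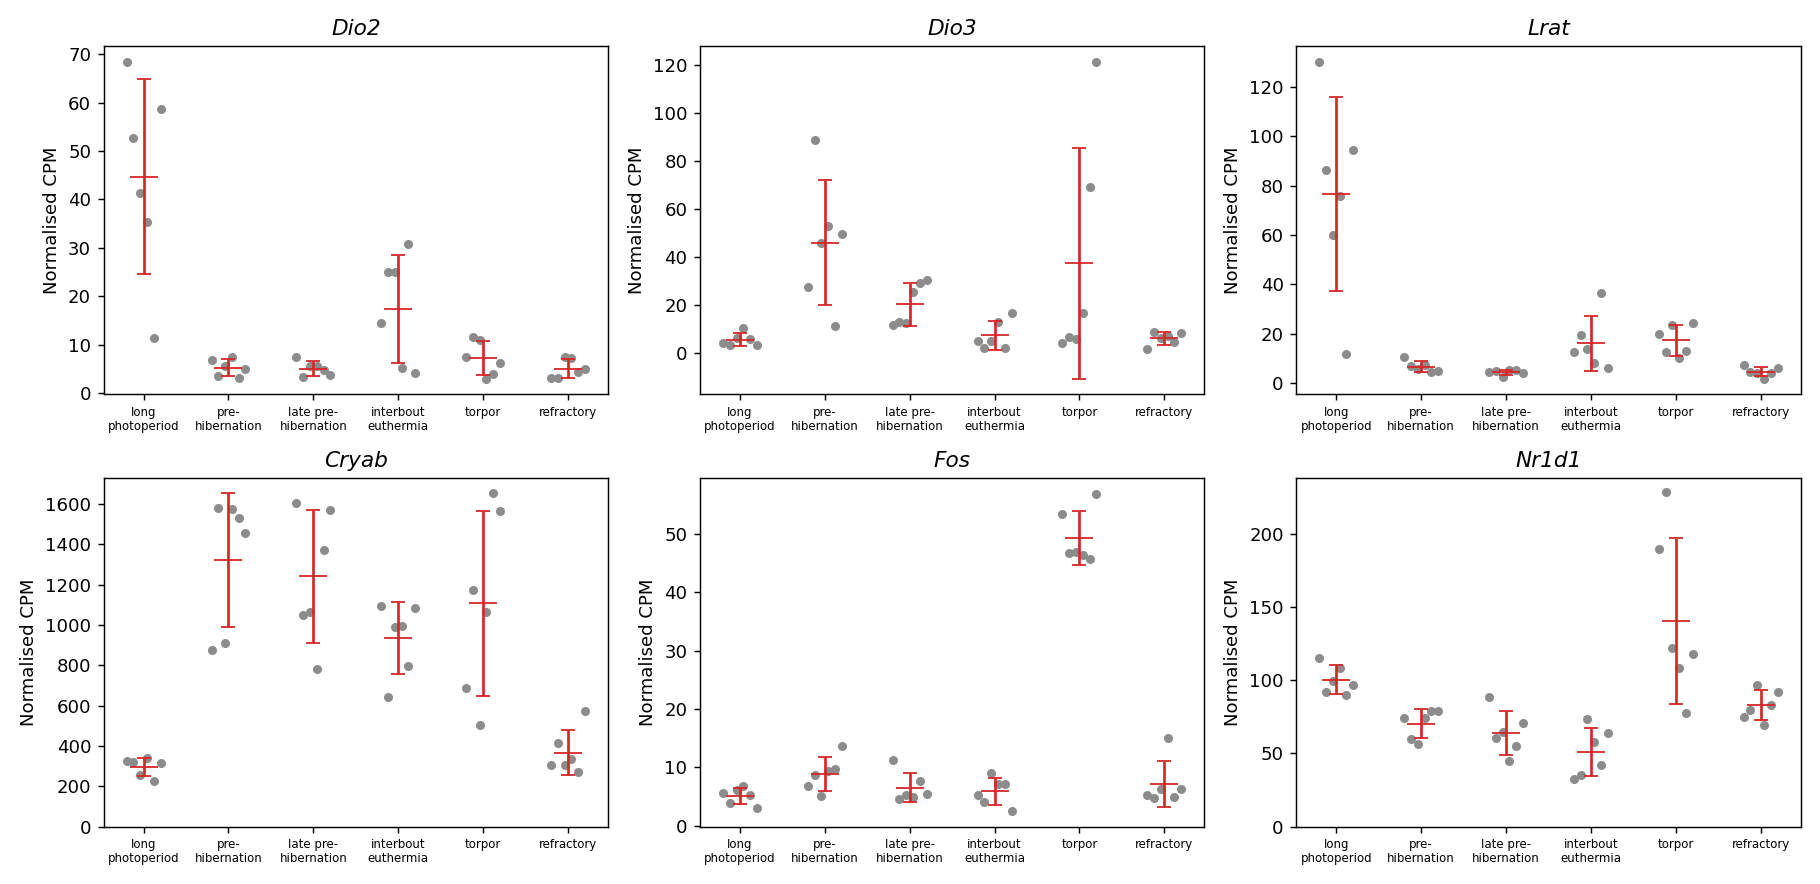
Normalised CPM of Dio2, Dio3, Lrat, Cryab, Fos and Nr1d1 in the 6 groups, with a point for each library and a red bar for the mean ± SD (n = 6). Dio2 and Lrat are highest on long photoperiod (44.7 and 76.5 CPM), Fos is at 49.4 CPM in torpor against 5.88 in interbout euthermia, and the Dio3 values in torpor scatter from library to library (SD 47.9 around 37.4).

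To ask what differed after 4 weeks of short days and cold, before any torpor, pre-hibernation was compared with long photoperiod. By the labels the pre-hibernation animals were also younger (4 against 8 months), so age cannot be told apart here. Dio2 was 8.37-fold lower (log2 fold change -3.07 ± 0.42, adjusted p = 1.45e-05) and Dio3 8.08-fold higher (3.01 ± 0.67, adjusted p = 0.00881), each with no overlap between the 6 and 6 libraries. Of the 15 genes of thyroid hormone signalling tested, 2 rose, 2 fell and 11 did not pass. Adjusted over the list alone, 4 rose and 5 fell. The other members that passed were Thrb, a thyroid hormone receptor (32.6 ± 6.14 to 77.9 ± 18.8 CPM, adjusted p = 0.00183), and Hr, a corepressor of such receptors (-0.65 ± 0.17, adjusted p = 0.0326). Hr lost its call in 7 of the 12 fits that left out 1 library, with the highest adjusted p without pre-hibernation 6 (0.0853). As a whole the list did not pass (adjusted p = 0.656).

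Lrat and Stra6 fell along with Dio2. Lrat, which stores retinol as esters, went from 76.5 ± 39.4 to 6.53 ± 2.30 CPM (-3.54 ± 0.41, adjusted p = 1.07e-06), and Stra6, a retinol transporter, from 489.8 ± 189.9 to 112.6 ± 39.3 CPM (-2.12 ± 0.50, adjusted p = 0.0144). These were the 2 of 16 retinoid genes that passed, while adjusted over the list alone 1 rose and 6 fell. The list was lower (adjusted p = 0.00829, and adjusted p = 0.206 with an estimated correlation). Its median log2 fold change was -0.22, and -0.39 without pre-hibernation 5. Gpr37l1, an orphan receptor, fell from 1075 ± 149 to 425.6 ± 62.3 CPM (adjusted p = 0.0002) and Ntsr2, a neurotensin receptor, from 220.2 ± 58.9 to 53.8 ± 7.47 CPM (adjusted p = 2.96e-06). Among the 37 nutrient, taste and hormone receptors, Gpr37l1 and the cation channel Trpv4 (-0.82 ± 0.20) fell and Trpv2, another cation channel, rose (1.32 ± 0.32). Trpv4 missed the threshold without long photoperiod 6 (adjusted p = 0.0536), and Trpv2 without long photoperiod 1 or 4 or pre-hibernation 2 (highest adjusted p 0.0577, without long photoperiod 4). That list as a whole did not pass (adjusted p = 0.346). Ntsr2 was the member of the 11 astrocyte markers that fell, with 3 falls adjusted over the list alone (list lower, adjusted p = 0.000137, and adjusted p = 0.271 with an estimated correlation).

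Cryab and Hspb1 rose at 4 weeks. Cryab, a small heat shock protein, went from 297.5 ± 44.9 to 1323 ± 334 CPM (2.15 ± 0.24, adjusted p = 1.07e-06), and Hspb1, of the same family, from 41.9 ± 7.59 to 157.4 ± 39.6 CPM (1.91 ± 0.30, adjusted p = 0.000128). With Hsf2, a heat shock transcription factor (1.01 ± 0.14), they were the 3 of 30 heat shock genes that rose, with none falling, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.763). Of the 20 glucocorticoid and stress response genes, Gadd45b (1.65 ± 0.34) and Ddit4, an inhibitor of mTOR signalling, rose (4 adjusted over the list alone). Ddit4 went from 87.2 ± 7.94 to 138.5 ± 14.7 CPM. That list was higher (adjusted p = 0.00829, and adjusted p = 0.206 with an estimated correlation). The largest rises also held Inhba, the activin beta A subunit (7.08 ± 2.26 to 68.8 ± 14.4 CPM, adjusted p = 3.93e-06), the cation channel Trpc5 (3.27 ± 0.58), the nicotinic receptor subunit Chrna3 (2.93 ± 0.48), the transcription factor Tbx2 (3.15 ± 0.56), Dnase2b (2.91 ± 0.59) and Tcerg1l (3.53 ± 0.81). The largest rise of all rested on 1 animal: Spp1 (osteopontin) stood at 206.3 ± 499.0 CPM in pre-hibernation against 1.59 ± 0.44, and its log2 fold change of 7.00 was 0.69 without pre-hibernation 2 (adjusted p = 0.766).

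Markers of neighbouring cell types were lower at 4 weeks. The 11 pituitary markers were lower (adjusted p = 1.13e-06, and adjusted p = 0.151 with an estimated correlation), with 2 falls, and 7 adjusted over the list alone. Growth hormone, Gh1, was at 90.4 ± 97.6 CPM on long photoperiod and 1.39 ± 2.37 in pre-hibernation (-6.33 ± 1.69, adjusted p = 0.0361), a call lost in 8 of the 12 fits that left out 1 library (highest adjusted p 0.0956, without pre-hibernation 4). Pou1f1, a pituitary transcription factor, passed as well (adjusted p = 0.0121), with means under 1 CPM in both groups. Motile cilia genes, markers of ependymal cells, had 0 of 47 changed members by edgeR, also adjusted over the list alone, and a median of -0.19 (adjusted p = 0.000179, and adjusted p = 0.637 with an estimated correlation). The 17 neuron markers (adjusted p = 0.000444) and the 11 oligodendrocyte markers (adjusted p = 0.021) were lower with no member passing, both with adjusted p = 0.637 with an estimated correlation. The oligodendrocyte call was lost without long photoperiod 5 (adjusted p = 0.0717), without pre-hibernation 5 (0.143) and without the 3 rRNA-rich libraries (0.113). Among 20 hypothalamic neuropeptides Kiss1 fell (-1.47 ± 0.35), and 4 fell adjusted over the list alone (list lower, adjusted p = 0.00829, and adjusted p = 0.635 with an estimated correlation). The mitochondrially encoded genes, which take a high share of the counts in pre-hibernation 5, had a median of 0.56, and -0.19 without the 3 rRNA-rich libraries.

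Further large falls were in Slc22a3, a transporter of organic cations (-2.20 ± 0.44), and Sik1, a salt-inducible kinase (-2.10 ± 0.37). Pla2g5, a phospholipase, passed (-3.46 ± 0.91), was at -0.26 without long photoperiod 5 (adjusted p = 0.968), and lost its call in 6 of the 12 fits that left out 1 library. In all, 289 genes rose and 122 fell by edgeR's quasi-likelihood test, and 637 rose and 504 fell without the 3 rRNA-rich libraries, with 399 genes shared in the same direction. With long photoperiod 1 to 3 alone as the reference 108 genes passed, and with 4 to 6 alone, whose files follow another naming pattern, 111. Without long photoperiod 4 the count was 263. The other 25 lists had adjusted p between 0.124 and 0.905. Of the fixed genes, Tshr, Gpr50, Rax, Vim, Nes, Rbm3, Cpt1a, Pdk4, Slc2a1 and Slc16a1 did not pass (adjusted p from 0.207 to 0.837). Vim stood at 1148 ± 36.2 and 1323 ± 217 CPM, and Rbm3 at 211.9 ± 10.7 and 246.5 ± 54.9 CPM, with adjusted p = 0.0197 for Rbm3 without the 3 rRNA-rich libraries.

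Late pre-hibernation was next set against pre-hibernation to ask what changed between 4 and 8 to 12 weeks. No gene passed: 0 of 17926 by edgeR, with 739 at an unadjusted p under 0.05, 4 by DESeq2 and 10 by limma voom. Neuron markers stood higher as a group, with 10 of 17 rising adjusted over the list alone and 0 over all genes tested. Syn1, of synaptic vesicles, went from 15.8 ± 4.95 to 27.6 ± 8.81 CPM and Uchl1, a neuronal ubiquitin hydrolase, from 122.1 ± 19.2 to 194.7 ± 69.4 CPM. The neuron list had adjusted p = 2.56e-14, and adjusted p = 0.142 with an estimated correlation. Its median of 0.65 was 0.39 without late pre-hibernation 4 (adjusted p = 5.74e-08).

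The 11 oligodendrocyte markers (median 0.57, adjusted p = 0.00377) and the 20 neuropeptides (0.37, adjusted p = 0.00636) were higher, calls lost with an estimated correlation (adjusted p = 0.472 for both). The 16 retinoid genes (-0.24, adjusted p = 0.00377), the 47 motile cilia genes (-0.08, adjusted p = 0.0109) and the 19 tanycyte markers (-0.15, adjusted p = 0.023) were lower, calls lost with an estimated correlation (adjusted p = 0.142, 0.962 and 0.788). None of the 5 lists had a changed member, also adjusted over the list alone. These 5 calls rested on single libraries. Without pre-hibernation 5, rich in rRNA, the oligodendrocyte (adjusted p = 0.105), retinoid (0.0664, median -0.09) and tanycyte (0.391, median -0.02) calls were lost. Without late pre-hibernation 4 the neuropeptide (0.205, median 0.10) and tanycyte (0.594) calls were lost and the oligodendrocyte median was 0.32, and the neuropeptide call was also lost without pre-hibernation 4. The tanycyte call was further lost without pre-hibernation 6 or late pre-hibernation 2, with medians from -0.34 to -0.02 over the 12 fits. The cilia call was lost without pre-hibernation 1, 2 or 3 or late pre-hibernation 1 (highest adjusted p 0.825, without the last), with medians from -0.13 to -0.02. The other 27 lists had adjusted p between 0.0505 and 0.956, and Dio3 was at -1.18 ± 0.62 (adjusted p = 1). Without late pre-hibernation 6 the count of changed genes was 1.

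To ask what the first torpor cycles left in the rewarmed animal, interbout euthermia was compared with late pre-hibernation. Dio2 was at 17.4 CPM against 5.07 (1.79 ± 0.40, adjusted p = 0.177), above every late pre-hibernation library in 4 of 6. Microglia and macrophage markers were higher as a group (median 0.44, adjusted p = 8.64e-08, and adjusted p = 0.459 with an estimated correlation), with 4 of 15 rising adjusted over the list alone. Csf1r, their growth factor receptor, was at 55 ± 18.5 CPM against 37.98 ± 10.9. Neuron markers were lower (median -0.43, adjusted p = 8.64e-08, and adjusted p = 0.459 with an estimated correlation), with 1 of 17 falling adjusted over the list alone, and Syn1 was at 11.4 ± 7.13 CPM. The neuron median was -0.18 without late pre-hibernation 4 (adjusted p = 0.00177). Motile cilia genes were higher (median 0.17, adjusted p = 5.13e-07, and adjusted p = 0.563 with an estimated correlation), with medians of 0.11 without late pre-hibernation 1 and 0.10 without interbout 5.

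Heat shock genes were lower (-0.10, adjusted p = 0.0037, and adjusted p = 0.733 with an estimated correlation), with 3 of 30 falling adjusted over the list alone and no call without late pre-hibernation 2 (adjusted p = 0.0804). Mitochondrially encoded genes had a median of 0.90 (adjusted p = 0.0173, and adjusted p = 0.733 with an estimated correlation). Interbout 6, rich in rRNA, has a high mitochondrial share, and without it the median was 0.03 (adjusted p = 0.974), and the call was also lost without late pre-hibernation 6. Neuropeptides (-0.29, adjusted p = 0.0173), mural cell and fibroblast markers (-0.18, adjusted p = 0.0203, 2 falls adjusted over the list alone) and oligodendrocyte markers (-0.19, adjusted p = 0.0431) were lower, with adjusted p = 0.563, 0.459 and 0.712 with an estimated correlation. The neuropeptide call was lost without late pre-hibernation 4 (0.389) or interbout 6 (0.0551), and the mural call without late pre-hibernation 4 (0.101) or interbout 6 (0.106, median -0.36). The oligodendrocyte call was lost in 6 of the 12 such fits, with the highest adjusted p without interbout 6 (0.549, median 0.03). The other 25 lists had adjusted p between 0.0801 and 0.933. No gene passed by edgeR, with 1104 at an unadjusted p under 0.05, 32 by DESeq2 and 550 by limma voom. Without interbout 6 alone the count was 25, without interbout 4 it was 2, and without the 3 rRNA-rich libraries it was 153, with 74 higher and 79 lower.

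Torpor was compared with interbout euthermia, its warm counterpart at the same age and day length. Several immediate early genes, which are transcribed within minutes of a stimulus, rose. Fos was 8.33-fold higher (5.88 ± 2.37 to 49.4 ± 4.62 CPM, adjusted p = 2.45e-09) and Egr1 5.38-fold (1.46 ± 0.61 to 7.83 ± 5.11 CPM, adjusted p = 0.000231), both above every interbout library in 6 of 6 animals. Junb (2.26 ± 0.45), Jun (1.86 ± 0.36), Zfp36, which marks messengers for decay (1.36 ± 0.16), and Csrnp1 (1.01 ± 0.17) rose too. Of 28 such genes 9 rose and none fell, and 11 rose and 4 fell adjusted over the list alone. The list was higher (adjusted p = 7.08e-05), with adjusted p = 0.0201 with an estimated correlation, and 0.13 in that form without the 3 rRNA-rich libraries.

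The clock repressor Nr1d1 rose from 50.9 ± 16.5 to 140.5 ± 56.4 CPM (adjusted p = 6.21e-06) and the clock repressor Cry1 fell from 23.8 ± 6.51 to 9.88 ± 1.83 CPM (-1.26 ± 0.14, adjusted p = 9.81e-08). With Ciart (1.02 ± 0.30, adjusted p = 0.0414), which lost its call in 9 of the 12 fits that left out 1 library (highest adjusted p 0.127, without torpid 1), they were the 3 of 23 clock genes that changed, 2 up and 1 down. The count adjusted over the list alone was the same, and the list did not pass (adjusted p = 0.93). The clock time of sampling is not given in the sources used here. Akap8l, a nuclear protein, rose from 43.5 ± 8.07 to 119.7 ± 17.5 CPM (adjusted p = 1.17e-08), and the cochaperone Dnajb5 rose (1.67 ± 0.21). Arrdc3, an arrestin family member, fell from 123.3 ± 37.2 to 36.9 ± 4.85 CPM (adjusted p = 2.73e-07) and Rsrp1 from 60.9 ± 17.1 to 16.7 ± 2.76 CPM (adjusted p = 5.11e-08). Kctd21 (-1.86 ± 0.20), the potassium channel Kcnj2 (-1.80 ± 0.23) and the homeobox gene Dlx5 (-1.92 ± 0.35) fell in 6 of 6 animals below every interbout library.

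Some calls were lost when 1 library was left out. Dio3 was 5.08-fold higher in torpor (2.35 ± 0.66, adjusted p = 0.0333), above every interbout library in 3 of 6, and at 1.48 without torpid 6 (adjusted p = 0.199). Its call was lost in 6 of the 12 fits that left out 1 library. Kmt2b, a histone methyltransferase (-1.74 ± 0.44), was at -1.14 without interbout 6 (adjusted p = 0.122). Alas2, an enzyme of haem synthesis in red cells (-2.81 ± 0.79), was at -1.88 without interbout 5 (adjusted p = 0.168) and was lost in 7 of 12 such fits, and Ptges, a prostaglandin E synthase (-1.57 ± 0.45), was lost in 8 of 12 (highest adjusted p 0.121, without interbout 2, at -1.32). The erythrocyte list, with 3 genes tested, had 1 fall over all genes and 2 adjusted over the list alone. Heat shock genes were higher (median 0.17, adjusted p = 0.0475, and adjusted p = 0.963 with an estimated correlation) with Hsph1 as the member that rose (0.70 ± 0.21), and 0 adjusted over the list alone. The list lost its call in 7 of the 12 fits (highest 0.173, without torpid 2) and Hsph1 in 10 of them (highest 0.226, without torpid 2, at 0.49).

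In all 202 genes rose and 526 fell in torpor. Without the 3 rRNA-rich libraries 594 rose and 1007 fell, with 707 shared in the same direction. The other 31 lists had adjusted p between 0.131 and 0.93. Dio2 was at -1.28 ± 0.40 (adjusted p = 0.0595), and passed without those libraries (-1.49, adjusted p = 0.0132). The RNA-binding protein gene Rbm3, induced by mild cold, stood at 245.2 ± 41.04 CPM in interbout euthermia and 321.6 ± 44.8 in torpor (0.39 ± 0.18, adjusted p = 0.296), with adjusted p = 0.026 without those libraries. The remaining fixed genes had adjusted p from 0.274 to 0.886, with Nes at adjusted p = 0.0157 without those libraries.

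To ask what distinguishes animals that had stopped hibernating, the refractory group was compared with interbout euthermia. Pygm, Cryab, Dct, Dio2 and Lrat were lower. Pygm, a glycogen phosphorylase, was at 25.5 ± 9.21 CPM against 97.2 ± 32.3 (-1.91 ± 0.32, adjusted p = 0.00177), and Cryab at 367.1 ± 112 against 934.8 ± 178 (-1.35 ± 0.23, adjusted p = 0.00177), both below every interbout library in 6 of 6. Dct, an enzyme of melanin synthesis, was at 1.98 ± 0.79 against 22.0 ± 9.63 CPM (-3.56 ± 0.54, adjusted p = 0.000742). Dio2 (-1.84 ± 0.41, adjusted p = 0.0167) and Lrat (-1.75 ± 0.40, adjusted p = 0.0169) fell, as did Hapln3 (-2.72 ± 0.46) and Dhrs7c (-2.69 ± 0.53). The neuropeptide genes Penk (5.21 ± 1.29 to 13.2 ± 4.24 CPM, adjusted p = 0.00487) and Cartpt (19.1 ± 6.99 to 54.1 ± 21.7 CPM, adjusted p = 0.019) rose, Cartpt with adjusted p = 0.0526 without interbout 4. Most calls of this comparison ended in 3 alternatives: 5 genes passed with the 2 groups alone, 44 with neuron and oligodendrocyte covariates and 106 with surrogate variables, against 628.

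Fuel metabolism genes were lower as groups. Of 32 genes of fatty acid oxidation and ketone metabolism 3 fell, Cpt1b (-1.52 ± 0.31), Cpt1c (-0.66 ± 0.15) and the carnitine carrier Slc25a20 (-0.57 ± 0.15), with 1 rise and 5 falls adjusted over the list alone. Slc25a20 missed the threshold without interbout 2, 3 or 4 (highest adjusted p 0.0615, without interbout 3). Of 21 glycogen genes Pygm and Phkg2, a subunit of the kinase that activates phosphorylase (-0.37 ± 0.09), fell, also adjusted over the list alone. Of 30 genes of sterol and fatty acid synthesis 1 fell, also adjusted over the list alone. Of 29 glycolysis and transport genes Eno2 fell (-0.54 ± 0.14; 2 adjusted over the list alone), with adjusted p from 0.0505 to 0.062 without interbout 1, 3 or 4 or refractory 4. The lists had adjusted p of 0.00049, 0.00398, 4.02e-05 and 0.000295 in this order, and adjusted p = 0.569, 0.355, 0.374 and 0.503 with an estimated correlation. Without refractory 4, rich in rRNA, their medians of -0.16, -0.13, -0.20 and -0.19 were -0.05, -0.13, -0.13 and -0.09, with adjusted p of 0.191, 0.0909, 0.00481 and 0.0631. Without interbout 6 the fatty acid median was -0.25.

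Refractory 4 also moved with other lower lists. Nuclear genes of oxidative phosphorylation (0 of 36 changed by edgeR, median -0.09, adjusted p = 0.0113) had a median of 0.05 without it (adjusted p = 0.155), heat shock genes (2 of 30 fell, Cryab and Hspb1, with 1 rise and 2 falls adjusted over the list alone, median -0.14, adjusted p = 0.00528) a median of 0.02 (0.398), and antioxidant genes (Gpx8 of 26 fell, 3 adjusted over the list alone, median -0.01, adjusted p = 0.0337) a median of 0.06 (0.772). With an estimated correlation these 3 lists had adjusted p = 0.748. The oxidative phosphorylation call was also lost without interbout 5 (0.102), with medians of -0.16 without interbout 6 and -0.15 without refractory 1. The antioxidant call was also lost without interbout 1 (0.0909) or 5 (0.128), with medians from -0.12 to 0.06 over the 12 fits. Hspb1 (-1.01 ± 0.29) was lost in 9 of 12 fits, with the highest adjusted p of 0.122 without refractory 4. Glucocorticoid and stress genes were lower (adjusted p = 0.0405, and adjusted p = 0.355 with an estimated correlation), with Ddit4 falling from 156.8 ± 20.4 to 87.1 ± 20.6 CPM and 2 falls adjusted over the list alone. That call was lost without interbout 1 or 6 and without refractory 2 or 5 (highest adjusted p 0.0909, without interbout 1).

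Several of the largest rises came with refractory 4. Titin, Ttn, was at 46.5 ± 109 CPM against 3.43 ± 2.62 (3.71 ± 1.05, adjusted p = 0.0423) and at -0.82 without refractory 4 (adjusted p = 0.461), its call lost in 6 of 12 fits. Vcan was at 0.15, Lrp1b at 0.23, Hmcn1 at 0.05, Abcb1 at 0.97 and Cntnap5 at 1.01 without it, against 2.29, 2.16, 2.07, 2.44 and 2.42 with it, with no call for any of these 5 (adjusted p from 0.0849 to 0.95). Their calls were lost in 5, 6, 6, 4 and 1 of the 12 fits. Of the 365 genes that rose, 311 had their highest refractory value in that library. Mural cell and fibroblast markers (3 of 15 rose, 5 with 1 fall adjusted over the list alone, adjusted p = 0.00646), endothelial markers (2 of 14 rose, also adjusted over the list alone, adjusted p = 0.0113) and choroid plexus markers (3 of 9 rose, 4 adjusted over the list alone, adjusted p = 0.0123) were higher in all 12 fits that left out 1 library. Without refractory 4 the mural median was 0.43 (adjusted p = 0.0458) and the endothelial median 0.34 (0.0493), and the highest choroid plexus adjusted p was 0.0409, without interbout 6. Without the 3 rRNA-rich libraries the calls were lost (adjusted p = 0.092, 0.092 and 0.0675), and the choroid plexus median of 0.67 was 1.27 without interbout 4. These 3 lists had, with an estimated correlation, adjusted p = 0.339, 0.431 and 0.33. Their rising members Abcc9, F5, Tmem72 and Prlr were at 0.40, 0.81, 0.51 and 0.77 without refractory 4, against 2.89, 2.36, 3.05 and 2.10, while Col1a1, Lum and Tek were at 2.01, 2.17 and 1.28 there, against 2.68, 2.79 and 1.67, and no longer passed (adjusted p = 0.113, 0.119 and 0.137). These 7 calls were lost in 5, 1, 6, 4, 6, 8 and 8 of the 12 fits in the order named. Lama2 (1.90 ± 0.54), an extracellular matrix gene, was at 0.31 without refractory 4 (adjusted p = 0.644), its call lost in 6 of 12 fits. Of 39 extracellular matrix genes 4 rose and 1, Timp1, fell (-0.65 ± 0.16), 6 and 1 adjusted over the list alone. Timp1 had adjusted p = 0.0539 without interbout 4, and the list did not pass (adjusted p = 0.19).

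Markers of other cells and hormones stood higher in the refractory group. The 17 neuron markers (median 0.47, adjusted p = 0.000415, no changed member), the 47 motile cilia genes (0.20, adjusted p = 0.00108, no changed member), the 20 neuropeptides (0.62, adjusted p = 0.00049, 3 rose, and 7 rose with 1 fall adjusted over the list alone) and the 11 oligodendrocyte markers (0.47, adjusted p = 0.00528, no changed member) were higher. With an estimated correlation the adjusted p was 0.491 for neurons and oligodendrocytes, 0.748 for cilia and 0.355 for neuropeptides. The oligodendrocyte call was lost without interbout 6 (adjusted p = 0.0819), with a median of 0.31 without interbout 4. Kiss1, the other neuropeptide that rose (1.19 ± 0.35), lost its call in 7 of 12 fits (highest adjusted p 0.121, without refractory 4). Of 11 pituitary markers 5 rose, and 6 with 1 fall adjusted over the list alone (adjusted p = 0.00237, and adjusted p = 0.355 with an estimated correlation). Gh1 was at 106.3 ± 208 CPM against 0.48 ± 0.59, and Cga and Lhb, subunits of the glycoprotein hormones, were at 3.45 and 0.83 without refractory 3, against 5.56 and 1.45 with it, with adjusted p = 0.15 and 0.127 there and calls lost in 8 and 5 of 12 fits. Fshb (adjusted p = 0.0278, lost in 6 of 12 fits, highest 0.152 without refractory 3) and Pou1f1 (adjusted p = 0.036, lost in 7, highest 0.0854 without interbout 3) passed near the detection floor in interbout euthermia.

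Of 16 retinoid genes Crabp1 (1.26 ± 0.24) and Rdh10 (0.95 ± 0.20) rose and Lrat fell (2 and 2 adjusted over the list alone, list adjusted p = 0.945). Of 15 thyroid hormone genes 3 fell, among them Dio2 and Thrb, and Slc7a8 rose, the same counts as adjusted over the list alone (list adjusted p = 0.655). Thrb went from 93.0 ± 35.1 to 46.6 ± 14.8 CPM, with adjusted p = 0.0526 without interbout 4. Slc7a8 (0.79 ± 0.23) was lost in 8 of 12 fits (highest adjusted p 0.144, without refractory 4). Of 23 clock genes 3 fell, among them Npas2 (-0.51 ± 0.14) and Timeless (-0.49 ± 0.14), and Nr1d1 (0.71 ± 0.20) rose, 4 and 2 adjusted over the list alone (list adjusted p = 0.467). Npas2 and Nr1d1 were lost in 6 of 12 fits (highest adjusted p 0.155 without interbout 3 and 0.092 without interbout 2) and Timeless in 8 (0.119 without refractory 4). Chrna3 (-1.73 ± 0.46) and the neurotrophin receptor Ngfr (-1.95 ± 0.48) fell, the first lost in 4 of 12 fits (highest adjusted p 0.0886, without refractory 4) and the second in 3 (0.06, without interbout 3). Of 19 tanycyte markers 2 fell, and 5 adjusted over the list alone (list adjusted p = 0.0968).

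In all 365 genes rose and 263 fell against interbout euthermia. Without the 3 rRNA-rich libraries 208 rose and 332 fell, and 235 genes were shared, 61 higher and 174 lower, so the balance of rises and falls turned with these libraries. It also turned with the 2 groups alone (0 up, 5 down), with covariates (9 up, 35 down), with surrogate variables (27 up, 79 down), with the replicate block (55 up, 164 down) and with voom (518 up, 652 down). Without refractory 4 alone 229 genes passed (74 up, 155 down), and without interbout 4 or 5 the balance turned as well (107 up and 115 down, 215 up and 245 down). Without refractory 1, 2 or 5 it was 440 and 194, 481 and 189, and 529 and 232. Without interbout 2, 3 or 4 the counts were 315, 253 and 222, and without refractory 3 or 6 they were 1000 and 1007. The other 17 lists had adjusted p between 0.0968 and 0.945, and the remaining fixed genes between 0.0746 and 0.934.

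The refractory group was last set against long photoperiod, given the same age in the labels but of uncertain age by the protocol, to ask how far the tissue had returned. Lrat (76.5 to 4.50 ± 1.86 CPM, -4.00 ± 0.42, adjusted p = 6.36e-07) and Dio2 (-3.19 ± 0.43, adjusted p = 9.37e-05) were still lower, in 6 of 6 animals below every long photoperiod library. Stra6 was at 152.8 ± 68.1 CPM. Lpl, lipoprotein lipase, was at 34.8 ± 7.61 against 129.9 ± 29.2 CPM (-1.90 ± 0.29, adjusted p = 0.000471), and Serpinf1 (PEDF) at 9.02 ± 2.66 against 63.7 ± 29.1 CPM (-2.83 ± 0.43, adjusted p = 0.000471). Dio3 did not pass (0.10 ± 0.66, adjusted p = 0.969), and Inhba was at 12.9 ± 5.70 against 7.08 ± 2.26 CPM. Higher were Uroc1, an enzyme of histidine breakdown (2.62 ± 0.48 to 5.97 ± 1.74 CPM, adjusted p = 0.00288), and Fgl2 (2.08 ± 0.46 to 5.08 ± 1.45 CPM, adjusted p = 0.0114).

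Of 16 retinoid genes 4 fell, among them Lrat, Rarb (-1.17 ± 0.23) and Rbp4 (-1.23 ± 0.28), and 6 adjusted over the list alone. The list was lower (adjusted p = 0.002, and adjusted p = 0.339 with an estimated correlation), with a mean of -0.63 but a median of 0.00 that went from -0.15 to 0.03 as single libraries were left out. Rbp4 lost its call in 6 of 12 fits (highest adjusted p 0.12, without long photoperiod 1). Dct (-2.94 ± 0.53) also fell, as did Edn3 (-1.74 ± 0.38), which lost its call without long photoperiod 2, 4 or 6 or refractory 4 (highest adjusted p 0.126, without long photoperiod 6). Lpl was the member of 24 lipid uptake genes that fell (4 adjusted over the list alone).

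Refractory 4 moved with most of the lists called here. Mitochondrially encoded genes had a median of 1.38 (0 of 11 changed by edgeR, 11 rose adjusted over the list alone, adjusted p = 0.000896, and adjusted p = 0.593 with an estimated correlation) and 0.13 without it. Heat shock (-0.20), fatty acid oxidation (-0.17), antioxidant (-0.13), sterol synthesis (-0.14), nuclear oxidative phosphorylation (-0.11), glycolysis (-0.10), glycogen (-0.12) and lipid uptake genes (median -0.02, mean -0.15) were lower, with adjusted p from 1.62e-05 to 0.0189, and from 0.593 to 0.637 with an estimated correlation. Without refractory 4 these 8 lists and the mitochondrial list did not pass, with medians from -0.05 to 0.03 in the lower lists and adjusted p from 0.0939 to 0.535 over the 9. Among these 8, the lipid list was the 1 with a changed member, over all genes or adjusted over the list alone. Endothelial markers (median 0.55, adjusted p = 0.00259, 2 of 14 rose adjusted over the list alone) and microglia markers (0.28, adjusted p = 0.0322, 0 of 15 changed by edgeR) were higher, the latter without a call when long photoperiod 3 (0.106) or 4 (0.0765) or refractory 1 (0.207) or 3 (0.2) was left out. The endothelial and microglia lists had adjusted p = 0.593 and 0.637 with an estimated correlation. The other 21 lists had adjusted p between 0.0932 and 0.889.

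In all 14 genes rose and 45 fell against long photoperiod. With RLE factors in place of TMM 102 rose and 63 fell, by DESeq2 195 rose and 135 fell, and without the 3 rRNA-rich libraries 15 rose and 80 fell, with 41 genes shared. The count ran from 23 without long photoperiod 6 to 413 without refractory 3. It was 30, 27, 37, 33 and 108 without long photoperiod 1, 2, 3, 4 and 5, and 41 (4 up, 37 down) without refractory 4. Without another refractory library the balance turned to rises: 279 up and 69 down (348) without refractory 1, 290 and 65 (355) without 2, 298 and 115 without 3, 311 and 84 (395) without 5 and 297 and 108 (405) without 6. With long photoperiod 4 to 6 alone as the reference it was 6.

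**Figure D3:**
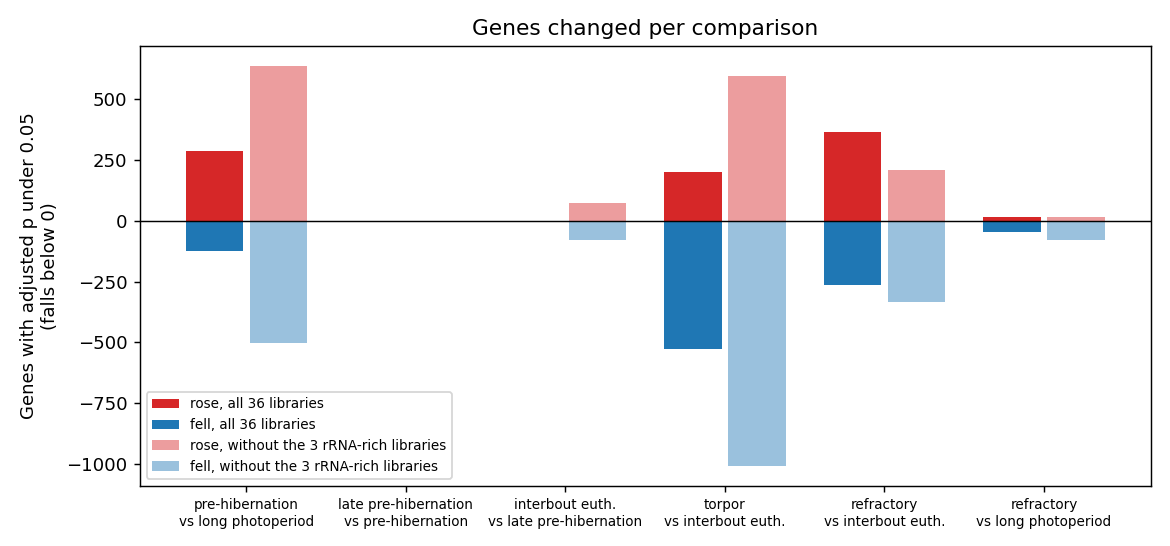
Genes that rose (above 0) and fell (below 0) at an adjusted p under 0.05 in the 6 main comparisons, with all 36 libraries and without the 3 rRNA-rich libraries. Leaving those out takes the count from 411 to 1141 in pre-hibernation against long photoperiod and turns the balance in refractory against interbout euthermia from 365 up and 263 down to 208 up and 332 down.

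Late pre-hibernation and interbout euthermia were also compared with long photoperiod, for counts and gene lists. In late pre-hibernation 403 genes rose and 239 fell (918 and 829 without the 3 rRNA-rich libraries, none of which is in either group). Retinoid genes were lower, with 7 of 16 falling and 1 rising, 8 and 1 adjusted over the list alone (adjusted p = 9.89e-06, and adjusted p = 0.0141 with an estimated correlation). Glucocorticoid and stress genes were higher, with 4 of 20 rising and 7 adjusted over the list alone (adjusted p = 7.96e-05, and adjusted p = 0.0141 with an estimated correlation). Motile cilia genes (adjusted p = 2.25e-08, 0 of 47 changed by edgeR), astrocyte markers (adjusted p = 0.00463, 1 of 11 fell, 3 adjusted over the list alone) and pituitary markers (adjusted p = 0.00059, 1 of 11 fell, 3 adjusted over the list alone) were lower, with adjusted p = 0.655, 0.655 and 0.387 with an estimated correlation. The astrocyte median of -0.32 was -0.59 without late pre-hibernation 4. The other 28 lists had adjusted p between 0.191 and 0.918. With long photoperiod 1 to 3 alone 270 genes passed, and with 4 to 6 alone 226.

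In interbout euthermia 217 genes rose and 115 fell against long photoperiod (481 and 366 without the 3 rRNA-rich libraries). Of 16 retinoid genes 5 fell and 2 rose, 8 and 3 adjusted over the list alone (adjusted p = 0.000911), and of 20 glucocorticoid and stress genes 1 rose, 5 adjusted over the list alone (list higher, adjusted p = 0.0118). With an estimated correlation these 2 had adjusted p = 0.117 and 0.142. Pituitary markers were lower (5 of 11 fell, also adjusted over the list alone, adjusted p = 1.83e-05), as were neuropeptides (1 of 20 fell, 5 adjusted over the list alone, adjusted p = 0.0118), neuron markers (0 of 17 changed by edgeR, adjusted p = 0.0118) and choroid plexus markers (1 of 9 fell, also adjusted over the list alone, adjusted p = 0.0491), and microglia markers were higher (0 of 15 changed by edgeR, adjusted p = 0.0118). With an estimated correlation the adjusted p was 0.142 for pituitary and choroid plexus genes, 0.52 for neuropeptides and 0.749 for neurons and microglia. Without interbout 5 the neuropeptide (0.0583), neuron (0.154, median -0.13 against -0.23) and microglia (0.0583) calls were lost, without interbout 2 the microglia call (0.142, median 0.21 against 0.36), and the neuron median was -0.40 without interbout 1. The choroid plexus call was lost in 5 of 12 fits (highest 0.0941, without interbout 6), with a median of -0.19 without long photoperiod 5 against -0.39. The other 26 lists had adjusted p between 0.0677 and 0.982. With long photoperiod 1 to 3 alone 102 genes passed (50 up, 52 down), and with 4 to 6 alone 56. Without long photoperiod 1 or 4 or interbout 3 or 4 the count was 187, 196, 195 and 178, and without long photoperiod 3 it was 215.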

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

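The tests chosen only after the result was seen are the count of splits for pre-hibernation against long photoperiod, the share of rises that are highest in refractory 4, the counts of genes shared between the 4-week and the refractory comparison, the ratio of Gh1 between refractory and pre-hibernation, the permutation tests of the pituitary list among animals on 10 h of light, and everything without the 3 rRNA-rich libraries.

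In each group of 6, a library was singled out when its gap to the nearest other library, as a share of the group's range, was above Dixon's 95% critical value for 6. This was done for 40 measures, which makes 240 groups, and chance singles out about 1 in 20 where values are normally distributed. CPM and percent shares were used untransformed, so that rate need not hold here. The rule picked out 43 values. Pre-hibernation 5 was far from its group in total counts (12.74 M, nearest 21.89), ribosomal RNA (9.278%, nearest 0.412), mitochondrial genes (11.78%, nearest 2.51) and the share of the top 10 genes (21.54%, nearest 5.76). Interbout 6 was far in the same measures (14.11 M against 22.1, 7.207% against 0.53, 14.3% against 2.721 and 21.5% against 5.71). Refractory 4 was far in ribosomal RNA (41.76% against 0.669), mitochondrial genes (18.27% against 3.208) and the top 10 genes (59.29% against 6.26), and torpid 4 in mitochondrial genes (3.179% against 2.493) and the top 10 genes (5.72% against 5.14).

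Of the gene levels, in CPM with the nearest library in brackets, the rRNA-rich libraries were far from their groups for 9 values apart from Gh1. In pre-hibernation 5 these were Akap8l, low at 32.74 (49.55), Rsrp1 84.99 (63.9), Penk 13.67 (5.912) and Rbm3, low at 139.3 (249.6). In interbout 6 they were Cry1 36.43 (23.22) and Ttn 8.629 (3.164), and in refractory 4 Fos 15.07 (6.31), Akap8l 88.04 (59.32) and Ttn 269.6 (2.717). Growth hormone, Gh1, was far in 5 groups: long photoperiod 2 at 282.4 (76.02), pre-hibernation 5 at 5.935 (2.076), late pre-hibernation 4 at 48.02 (5.801), torpid 3 at 7.88 (0.2191) and refractory 3 at 524.8 (86.9). Spp1 was far in pre-hibernation 2 at 1225 (4.586), interbout 2 at 6.972 (2.956) and refractory 3 at 51.68 (5.49). Late pre-hibernation 4 was high in the neuronal genes Syn1, 45.03 (27.89), and Uchl1, 331.1 (191), and pre-hibernation 6 in Syn1, 24.84 (15.83).

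Long photoperiod 6 was high in Thrb, 44.62 (31.77), Ddit4, 102.2 (88.43), and Lpl, 185.6 (131), and long photoperiod 2 in Ttn, 7.147 (3.136). Torpid 2 was high in Egr1, 17.67 (8.092), and Dct, 66.61 (22.67), and torpid 6 was low in Csf1r, 31.01 (44.96). The other 3 were Ddit4 in late pre-hibernation 5, 187.5 (135.9), Arrdc3 in interbout 3, 195 (126.8), and Lrat in late pre-hibernation 3, low at 2.379 (4.149).

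The genes that rose in the refractory group against interbout euthermia had their highest refractory value in refractory 4 for 85.2% of them (311 of 365), where 16.7% is the share by chance, and 146 of the 263 genes that fell had their lowest value there (55.5%). Low depth does not account for the number of genes detected in refractory 4: 0 of the 35 other libraries, thinned to its total, detected as many (27113 against 18649 to 20943). That outcome was fixed in advance, since the highest other library at full depth, long photoperiod 2, detected 25416. Whether low depth raised the values of the called genes was not tested. Counts spread over the genome, as from DNA or unspliced RNA, cannot be told apart from other sources. Over 4052 protein-coding genes picked for a mean under 0.05 CPM in the other 35 libraries, so that low values there are partly fixed by the choice, refractory 4 held a mean of 1.18 CPM against 0.0157 in the median of the others (75 times, highest other 0.0373). The Spearman correlation of the counts of these genes with exon length was 0.22 in refractory 4 (highest other 0.176). The other libraries hold few counts on these genes by the choice, so their correlations are no yardstick for refractory 4. A candidate explanation for these rises is thus the state of 1 library, and no biological explanation was tested.

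The genes that rose at 4 weeks tended to be lower in the refractory group than in interbout euthermia, though the comparisons share no library. In all, 69 were shared where 4.2 were expected by chance (Fisher's exact p = 9.38e-65), and 105 against 11.8 without the 3 rRNA-rich libraries (Fisher's exact p = 5.39e-71). Fisher's test takes genes as independent units, so genes that vary together make its p too small, and it does not measure the spread over animals. Regrouping the libraries did not exclude chance for the refractory count with all 36 libraries. No gene rose in both comparisons (0, where 5.9 were expected). Of the genes that fell at 4 weeks, 12 rose in the refractory group (2.5 expected) and 4 fell (1.8 expected). Genes of low spread can be called in either direction, so these counts do not exclude that low spread adds to the overlap. Between 4 and 6 months the refractory falls had a median change of -0.006 (quartiles -0.095 and 0.108), against their own -0.678. A steady fall with age would show there if nothing else changed. Time on short days differs between those groups too and could offset it, so the value does not decide on age. In both overlapping comparisons the lower group was the older by the labels, at 8 months. With neuron and oligodendrocyte marker levels as covariates the median of the 4-week rises was -0.317, against -0.499 without. A short photoperiod rise that has ended in the refractory stage may explain the overlap, while an age effect, steady or of another shape, stays open, untested.

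The pituitary markers that were lower at 4 weeks varied together from library to library: within groups, Gh1 went with the mean of 4 other pituitary genes with a Spearman rho of 0.70 (permutation p = 0.00017, 36 libraries) and a Pearson r of 0.681 (permutation p = 0.00024), and 0.561 without the 2 libraries farthest from the rest. Pituitary tissue in some of the captured strips is a candidate source. If day length were the whole cause, the 5 groups on 10 h of light would not differ, yet the mean of all 11 pituitary markers differed among them (30 libraries, permutation p = 0.0154). That test was taken up after a first one, of Gh1 in refractory against pre-hibernation, had missed the threshold (exact p = 0.0606). Pituitary tissue captured unevenly would also make these groups differ, so the test does not decide what part day length has. The mean of the 11 markers was higher by 1.31 on the log2 scale in refractory than in interbout euthermia (exact p = 0.013 for 6 against 6). Gh1 itself rose in that comparison (7.85, adjusted p = 0.019, kept in 12 of 12 fits that left out 1 library), though not by voom (adjusted p = 0.425 for Gh1, refractory vs interbout euthermia) or with the 2 groups alone (0.244). Against pre-hibernation its median in refractory was 84.3 times higher (12.8 against 0.151 CPM), with an exact p of 0.0606. A part set by day length, and the age and stage of the animals, stay open, untested.

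For each count of changed genes, 100 splits of the same libraries into groups of the same sizes were drawn, the real one included. Chance was made unlikely where only the real split reached the count, 1 of 100, the lowest share that these splits can show. These counts were 411 genes in pre-hibernation against long photoperiod (highest other split 10), 728 in torpor against interbout euthermia (49), 642 in late pre-hibernation against long photoperiod (131), 332 in interbout euthermia against long photoperiod (79) and 2625 among all 6 groups (1139). Chance was not excluded for refractory against interbout euthermia, where 5 of 100 splits reached 628 genes (highest other 2036), or against long photoperiod, where 41 of 100 reached 59 (highest other 745). Splits that call several times the real count point to a structure of the samples. With 0 genes changed, late pre-hibernation against pre-hibernation and interbout euthermia against late pre-hibernation were reached by 100 of 100 (highest other 0 and 3). Without the 3 rRNA-rich libraries only the real split reached the 153 genes of interbout euthermia against late pre-hibernation (1 of 100 splits, highest other 88). That setting was chosen after seeing the data, and with all libraries the count was 0, so chance was made less likely but was not excluded. In that setting 2 of 100 splits reached the 540 genes of refractory against interbout euthermia (highest other 552). Against long photoperiod 3 of 100 reached the 95 genes of the refractory group (highest other 465). Splits other than the real one reached both refractory counts, so chance was made less likely there but was not excluded. Against long photoperiod a split again called several times the real count.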

How the results depend on the processing

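The tests chosen only after the result was seen are those without the 3 rRNA-rich libraries and with ribosomal RNA and mitochondrial genes removed. Over the alternatives other than leaving out 1 library, called genes kept their direction and their side of the threshold in 1008 tests, kept the direction but not the call in 278 and changed direction in 6. Where DESeq2 gave a gene no adjusted p, the test was counted as kept if the direction held. The 1008 can therefore include tests in which the call was not assessed. For called lists these were 575, 110 and 8. Leaving out 1 library gave 1088, 243 and 1 for genes and 698, 66 and 4 for lists. Under the alternatives other than leaving out 1 library, genes not called passed in 137 tests. Lists not called passed there in 88 tests with the direction kept and in 2 more with the direction turned. When 1 library was left out these were 49 tests for genes and 79 for lists. The same gene or list can count several times. Neuron and oligodendrocyte lists were not tested with their own means as covariates. The cause of the changes below was not tested, except that fits of fewer libraries have fewer samples.

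Counts are given in the order named. For pre-hibernation against long photoperiod (411 genes) they were 637 by DESeq2, 2102 by voom, 263 with no filter, 815 with surrogate variables, 697 with the 2 groups alone, 108 with long photoperiod 1 to 3, 111 with 4 to 6 and 1141 without the 3 rRNA-rich libraries. For late pre-hibernation against pre-hibernation (0) they were 4 by DESeq2 and 10 by voom. For interbout euthermia against late pre-hibernation (0) they were 32 by DESeq2, 550 by voom, 12 with covariates, 53 with surrogate variables and 153 without the 3 libraries. For torpor against interbout euthermia (728) they were 1153 by DESeq2, 1927 by voom, 482 with no filter, 1531 with surrogate variables and 1601 without the 3 libraries. For refractory against interbout euthermia (628) they were 972 by DESeq2, 1170 by voom, 390 with the CPM filter, 2026 with no filter, 44 with covariates, 106 with surrogate variables and 5 with the 2 groups alone. For refractory against long photoperiod (59) they were 330 by DESeq2, 186 by voom, 165 with RLE, 6 with long photoperiod 4 to 6, 9 with the 2 groups alone and 95 without the 3 libraries. For late pre-hibernation against long photoperiod (642) they were 3071 by voom, 1479 with surrogate variables, 1338 with the 2 groups alone, 270 and 226 with long photoperiod 1 to 3 or 4 to 6 and 1747 without the 3 libraries. For interbout euthermia against long photoperiod (332) they were 614 by DESeq2, 1543 by voom, 203 with no filter, 689 with surrogate variables, 102 and 56 with long photoperiod 1 to 3 or 4 to 6 and 847 without the 3 libraries. Among all 6 groups (2625) they were 4172 by DESeq2, 7787 by voom, 5943 with no filter and 4952 without the 3 libraries. With no filter the median of all genes was 0.155 in refractory against interbout euthermia, where it was 0.022 with the filter, and 0.139 against long photoperiod, where it was 0.025. With ribosomal RNA and mitochondrial genes removed the counts were 417, 0, 0, 751, 611, 54, 635, 333 and 2613 in this order.

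The balance of rises and falls moved too. Against 289 and 122, voom gave 1134 and 968 and surrogate variables 461 and 354 in pre-hibernation against long photoperiod. Against 202 and 526, they gave 840 and 1087, and 599 and 932, in torpor. Against 365 and 263 in refractory against interbout euthermia, voom gave 518 and 652, no filter 1663 and 363, covariates 9 and 35 and surrogate variables 27 and 79. Against 14 and 45 in refractory against long photoperiod, covariates gave 25 and 41 and long photoperiod 1 to 3 gave 2 and 38. Against 403 and 239 in late pre-hibernation, voom gave 1579 and 1492 and surrogate variables 724 and 755, and against 217 and 115 in interbout euthermia they gave 812 and 731, and 378 and 311.

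With the replicate block, the counts in the same order were 359, 0, 0, 634, 219, 46, 602, 277 and 1915, with 55 up and 164 down in refractory against interbout euthermia and 5 up and 41 down against long photoperiod. Animals were not paired: libraries with the same number correlated between -0.329 and 0.265 after group means were removed.

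Leaving out 1 library gave 263 to 381 genes for pre-hibernation against long photoperiod, 0 to 1 for late pre-hibernation against pre-hibernation, 0 to 25 for interbout euthermia against late pre-hibernation, 556 to 701 for torpor against interbout euthermia, 222 to 1007 for refractory against interbout euthermia, 23 to 413 for refractory against long photoperiod, 464 to 735 and 178 to 362 for late pre-hibernation and interbout euthermia against long photoperiod and 2255 to 3169 among all 6 groups.

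Genes whose change turned sign were Pla2g5 in pre-hibernation against long photoperiod (0.287 with long photoperiod 1 to 3), and in refractory against interbout euthermia Ttn (-0.402 with voom, -0.356 with surrogate variables, -0.331 without the 3 libraries, -0.819 without refractory 4) and Vcan (-0.1 with voom, -0.099 with surrogate variables). For lists, the direction of the test turned in the following, given as medians, whose sign can differ from that of the test. These were mitochondrially encoded genes in pre-hibernation against long photoperiod (-0.193 without the 3 libraries, 0.56 with them) and, with covariates, tanycyte markers (-0.008 against -0.15) and neuropeptides (-0.070 against 0.37) in late pre-hibernation against pre-hibernation and neuropeptides in interbout euthermia against late pre-hibernation (0.044 against -0.29). In refractory against interbout euthermia they were heat shock genes (-0.015 with voom, 0.048 with surrogate variables, -0.009 without the 3 libraries, 0.017 without refractory 4, against -0.14), nuclear oxidative phosphorylation (0.051 against -0.09) and antioxidant genes (0.057 against -0.01), both without refractory 4. In refractory against long photoperiod they were nuclear oxidative phosphorylation (0.003 with voom, 0.026 without the 3 libraries, 0.032 without refractory 4, against -0.11) and primary cilium genes (0.048 with voom). Medians of other called lists crossed 0 while the test kept its direction. Among the fits leaving out 1 library, these included lipid uptake (0.028) and glycolysis (0.001) without refractory 4 and retinoid genes (0.023 without refractory 5) in refractory against long photoperiod, and oligodendrocyte markers in interbout euthermia against late pre-hibernation (0.025 without interbout 6). As single libraries were left out, Ttn went from -0.819 to 4.17 in refractory against interbout euthermia, and the medians there from -0.163 to 0.051 for nuclear oxidative phosphorylation, from -0.177 to 0.017 for heat shock and from -0.123 to 0.057 for antioxidant genes, and against long photoperiod from -0.159 to 0.032 for nuclear oxidative phosphorylation. The library of lowest depth, refractory 4 with 5.16 M counts, limits what can be said of the refractory group.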

Other observations

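The tests chosen only after the result was seen are the gene changes without the 3 rRNA-rich libraries.

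Interbout euthermia was compared with late pre-hibernation once more without the 3 rRNA-rich libraries, where 74 genes rose and 79 fell, and genes were named by the rule used elsewhere. Dio2 and Lrat were higher: Dio2 at 1.98 ± 0.40 (adjusted p = 0.0124; 1.79 and adjusted p = 0.177 with all 36 libraries) and Lrat at 2.06 ± 0.40 (adjusted p = 0.0111; 1.89 and 0.177). Ptges, a prostaglandin E synthase, was at 2.47 ± 0.48 (adjusted p = 0.0111), and the macrophage marker Adgre1 at 1.39 ± 0.25 (adjusted p = 0.011). The other large rises were Ubd (1.24), Pkp1 (1.14), Gper1 (1.05) and Angptl4 (0.99). The histamine receptor Hrh3 was lower (-1.91 ± 0.28, adjusted p = 0.00175; -1.19 and 0.441 with all 36 libraries). So were the synaptic gene Syn1 (-1.55 ± 0.35, adjusted p = 0.0325; -1.29 and 0.333) and Hspb1 (-1.30 ± 0.30, adjusted p = 0.0358; -1.04 and 0.335). Arsl (-2.18), Plekhh3 (-1.55) and Cdh22 (-1.46) were lower too, and at -1.48, -1.05 and -0.90 with all 36 libraries. Tbx2 (-1.67) was at -0.29 with all 36 libraries.

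Several gene groups passed in none of the 8 comparisons. Ribosomal protein genes (75 tested, adjusted p from 0.126 to 0.79) had no changed member by edgeR. Thyroid hormone signalling (15, 0.301 to 0.918), primary cilium genes (35, 0.159 to 0.889), nutrient, taste and hormone receptors (37, 0.128 to 0.945), clock genes (23, 0.128 to 0.93), hypoxia response (19, 0.0932 to 0.935), cell cycle (25, 0.519 to 0.918), extracellular matrix (39, 0.118 to 0.982), barrier genes (20, 0.389 to 0.85) and oligodendrocyte precursor markers (6, 0.0505 to 0.806) did not pass either. Erythrocyte markers, with 3 genes tested, had medians from -2.81 in torpor against interbout euthermia to 1.505 in interbout euthermia against late pre-hibernation.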
